A study of Mus musculus with 2 samples.

How the data were processed

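H3K9me3, histone H3 trimethylated at lysine 9, was measured by chromatin immunoprecipitation and sequencing in forebrain of mouse embryos at day 13.5. Per the labels, the tissue came from strain B6NCrl and pooled both sexes. Both samples belong to 1 group and are biological replicates 1 and 2, with separate biosamples but a shared donor label; replicate 1 combined 2 technical replicates and replicate 2 had 1. The labels give a fragment size range of 300 to 500 bp. A comparison between groups was not possible with 1 group, and p-values measure where peaks lay in these samples, not variation across animals.

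The data used here are 4 peak lists on assembly mm10 in narrowPeak layout. Per the text deposited with the files, the authors derived the list of each replicate from that replicate's alignments and a control, the pooled list from both replicates and both controls, and the replicated list from the other lists. The aligner, the peak caller, its version and its thresholds are not given in the sources used here. For each peak the authors give a fold enrichment over the control, a ratio that was used as deposited. The authors also give −log10 p and −log10 q for each peak, and these deposited values served mainly to rank, filter or describe peaks within a list. An exception was a test on chromosome X, which compared −log10 p between the lists of the replicates. No read counts were used here, so the sequencing depth behind each peak is unknown and no interval on a single fold enrichment can be given. A list made from fewer reads misses weak peaks, and a peak list made for sharp peaks breaks a broad mark into many short intervals, so the number and width of peaks depend on the depth and the caller.

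Peaks were compared with the mouse reference genome GRCm38, the assembly also called mm10, and with GENCODE gene models, release M21. No peak reached past the end of its chromosome, and no list held overlapping peaks. Analyses covered 21 chromosomes (1 to 19, X and Y); peaks on unplaced or unlocalized sequences were counted separately. Coordinates are 1-based. Scripts ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and samtools 1.23.1 indexed the genome.

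Peaks of the replicates counted as shared when the overlap reached 50% of either interval. The observed share was compared with 10000 circular shifts, in which all peaks of a chromosome moved together by a random distance with the first 3 Mb of the chromosome left out. The shifts keep the widths and spacing of peaks, and gene positions stay in place. The permutation test was one-sided for the overlap and two-sided elsewhere; 10000 shifts give a two-sided p of 2.0e-04 at the smallest. Gene groups were tested at the gene body (an overlap of 1 bp or more), at the promoter (1 kb either side of the transcription start site, TSS) and over the last exon of the longest transcript. P-values were adjusted by Benjamini-Hochberg over the 15 groups within each zone, with a threshold of 0.05. Fisher's exact test against all other protein-coding genes was run as an alternative for gene bodies; it ignores gene length. Feature shares used peak summits and protein-coding genes only, with promoter taking precedence over exon, exon over intron and intron over intergenic. Peak strength was described as the percentile of a group's median fold enrichment among 10000 random sets of genes with a peak. Domains were replicated peaks merged at gaps of 10 kb or less, and covered bases were also summed in 1 Mb windows. Base composition was compared with 100 shifts, whose smallest two-sided p is 2.0e-02.

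The 15 gene groups, the rule for naming genes, the main tests and most alternatives were chosen before the data were examined. Symbol patterns defined zinc finger genes (Zfp, Zkscan, Zscan and Zik1), clustered protocadherins, olfactory receptors, vomeronasal receptors, Hox, histone and ribosomal protein genes. Lists by name defined imprinted genes, germline genes, forebrain transcription factors, neuronal genes, genes of other lineages, vascular and microglial genes (with some of connective tissue), pluripotency and 2-cell genes, and the machinery that writes, reads or removes H3K9me3. The lists overlap: Rpl10l counts as germline and ribosomal, and Zfp42 and Zscan4 genes as pluripotency and zinc finger. Every listed symbol was found in the annotation except Tasor, whose older symbol Fam208a was also listed. The rule for naming genes took the 25 protein-coding genes with the highest fold enrichment of a peak present in both replicates. It also took up to 8 imprinted, germline, forebrain transcription factor and H3K9me3 machinery genes with a promoter peak, the 3 genes with the highest fold enrichment in each other group, the 10 widest domains and the 10 densest windows. Genes named outside this rule are described as such where they appear.

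The shift test was tested on simulated data. With the real peaks moved at random 100 times, 2.93% of the group tests at gene bodies, 1.87% at promoters and 2.07% over last exons passed an unadjusted p of 0.05 with 200 shifts each; this number of shifts is too small to test the adjusted calls. With peaks added at the promoters of 10% of 200 random genes, all 20 simulated sets passed the unadjusted threshold. These sets were larger than most of the 15 groups and spread over the genome. Whether the test detects an effect in small or clustered groups after adjustment was therefore not tested. With 25% of replicate 1 peaks planted into a moved copy of the list, 25.8% were recovered as shared. Alternatives were a −log10 q of at least 2, peaks present in both replicates' lists, each replicate's list alone, other overlap rules, the 20000 peaks with the smallest p, a promoter window of 2.5 kb, the last 2 kb of the gene and merging gaps of 5 and 20 kb. For promoters and last exons, the stricter list, the peaks in both replicates and the single-replicate lists were chosen after seeing the data, as were the split of protocadherins into subclusters, the breakdown of zinc finger genes by zone and chromosome, the comparison of last exons with the 50 kb on either side of the genes (bootstrap over 1 Mb blocks), the limit of 10 genes for describing changes in peak strength, and the 6 chromosomes carried through the alternatives.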

Results

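H3K9me3, a histone mark of heterochromatin, was mapped in the forebrain of mouse embryos at day 13.5, a stage at which neurons are being generated. The design had 1 group of 2 biological replicates and no second condition, so the comparisons asked where in the genome the mark lay, which genes carried it and how far the replicates matched. Peak lists of each replicate and of the pooled data were analysed (assembly mm10), and so was the replicated list that the authors derived from them. The fold enrichment of each peak over the control was used as the authors gave it. No read counts were used, so sequencing depth is unknown, and the tests measure where peaks lay in these samples, not variation across animals.

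The replicates yielded similar numbers of peaks, 72627 in replicate 1 and 74268 in replicate 2. Most peaks were narrow and weak, with median widths of 219 and 224 bp and median fold enrichments of 3.17 and 3.26. The pooled list held 90409 peaks and the replicated list 34268, the latter with a median width of 407 bp (quartiles 301 and 587) and a median fold enrichment of 3.59. Replicated peaks covered 17.3 Mb of the chromosomes, or 0.633% of their length. A −log10 q of at least 2 was reached by 28.1% of the peaks of replicate 1, 31.5% of those of replicate 2 and 93.5% of the replicated peaks.

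Each replicate shared about the same part of its peaks with the other. Of the replicate 1 peaks on chromosomes, 32.03% overlapped a replicate 2 peak, and 30.8% of the replicate 2 peaks overlapped a replicate 1 peak. Shifted peaks gave a mean of 1.20% and at most 3.21% for replicate 1 (permutation test, one-sided, p = 1.0e-04, the smallest that 10000 shifts give). With 50% of both intervals required to overlap, the shares were 20.2% and 19.8%. The base-pair Jaccard index of the replicates' lists was 0.201. Fold enrichments of the 24934 replicated peaks touching a peak in both replicates by at least 1 bp were weakly related (Spearman's rho 0.269, Pearson's r of log2 values 0.306, across peaks, which are not independent replicates). Over 2737 windows of 1 Mb, the bases covered in the replicates were closely related (rho 0.903, r 0.994, across windows). All 34268 replicated peaks were identical in position and fold enrichment to a pooled peak. Of those on chromosomes, 84.3% overlapped a peak of replicate 1, 87.3% a peak of replicate 2 and 72.7% a peak of both. When 50% of both intervals had to overlap, the share found in both replicates was 40.8%.

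Chromosome 7 carried the densest H3K9me3, with 20.9 kb of replicated peaks per Mb, against 6.33 kb per Mb over the genome. Chromosomes 17 and 4 followed at 12.6 and 10.1 kb per Mb, and chromosome 15 was the lowest autosome of the replicated list at 3.11 kb per Mb. In the single-replicate lists, chromosome 7 reached 20.2 ± 1.12 kb per Mb, chromosome 17 reached 13.5 ± 0.888, chromosome 4 reached 10.7 ± 0.563 and chromosome 15 reached 4.74 ± 0.0499 (mean ± SD, n = 2), so the gaps between these chromosomes exceeded the spread between replicates. Chromosome 14 was as low as chromosome 15 in these lists, at 4.74 ± 0.0791. Chromosome X had 1.77 kb per Mb of replicated peaks and chromosome Y 0.104 kb per Mb. Both sexes were pooled, and full lengths were used although reads cannot be placed in some repeats. A low peak density on X or Y therefore does not show a low level of the mark. Chromosome X was also the one on which the replicates differed most. Replicate 1 had 1781 X peaks, 2.46% of its peaks (exact Clopper-Pearson 95% interval 2.35 to 2.58), and replicate 2 had 2984, 4.04% (3.90 to 4.19); these intervals cover counting error only. The covered length per Mb of X was 1.68 times as large in replicate 2, while on the autosomes this ratio lay between 1.00 and 1.10.

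**Figure D1:**
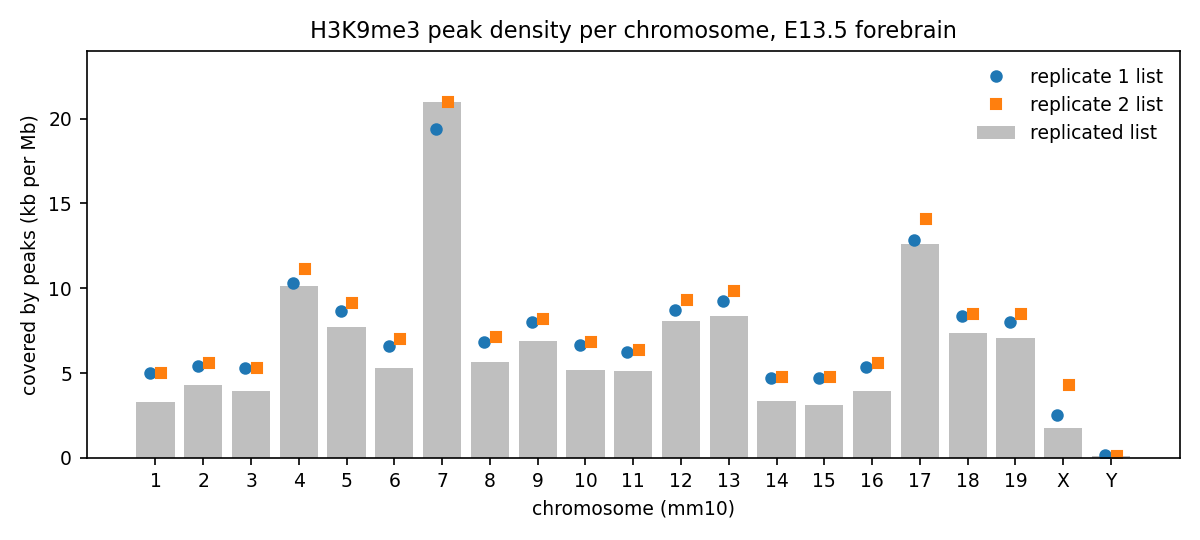
Bases covered by H3K9me3 peaks per Mb (kb per Mb, y axis) on each mouse chromosome (x axis); grey bars are the replicated list, blue circles the replicate 1 list and orange squares the replicate 2 list. Chromosome 7 stands highest at 20.9 kb per Mb in the replicated list, and the replicates lie apart on X (2.55 and 4.29 kb per Mb).

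H3K9me3 peaks lay mostly outside protein-coding genes. Only these genes were used for the classes, so intergenic here includes genes of other types. Of 33976 replicated peak summits, 68.9% were intergenic, 24.4% in introns, 3.54% in exons and 3.21% in promoters of protein-coding genes. Shifted summits gave 58.1 ± 1.74% intergenic, 34.9 ± 1.56% intronic, 2.91 ± 0.206% exonic and 4.18 ± 0.349% promoter (mean ± SD of the shifts). Intergenic and exonic summits were thus above the shifts and intronic and promoter summits below them (permutation test, two-sided; adjusted p = 4.0e-04 for intergenic and intron, 3.2e-03 for exon and 3.6e-03 for promoter). Each replicate's list alone gave the same directions.

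Among the 15 gene groups, clustered protocadherins, imprinted genes, germline genes, zinc finger genes and vomeronasal receptors carried more peaks over their bodies than shifted peaks gave. At promoters the excess was in protocadherin, imprinted and germline genes, and over last exons in zinc finger, vomeronasal, imprinted and olfactory receptor genes. Hox and histone genes had no replicated peak in any zone, and no further group passed the test. For scale, 17.9% of 21938 protein-coding genes had a replicated peak over the body, 2.60% at the promoter and 3.29% over the last exon. Ratios were lower in the longer single-replicate lists, where the promoter calls held: 18.4 and 16.6 for protocadherins in replicates 1 and 2, 9.53 and 9.69 for germline genes, and 6.47 in replicate 1 for imprinted genes. The last-exon calls of zinc finger and imprinted genes also held, with the lowest ratios, 3.37 and 3.46, in replicate 1. A promoter window of 2.5 kb gave 19.2 for protocadherins, 8.40 for germline genes and 6.65 for imprinted genes, all still past the test.

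**Figure D2:**
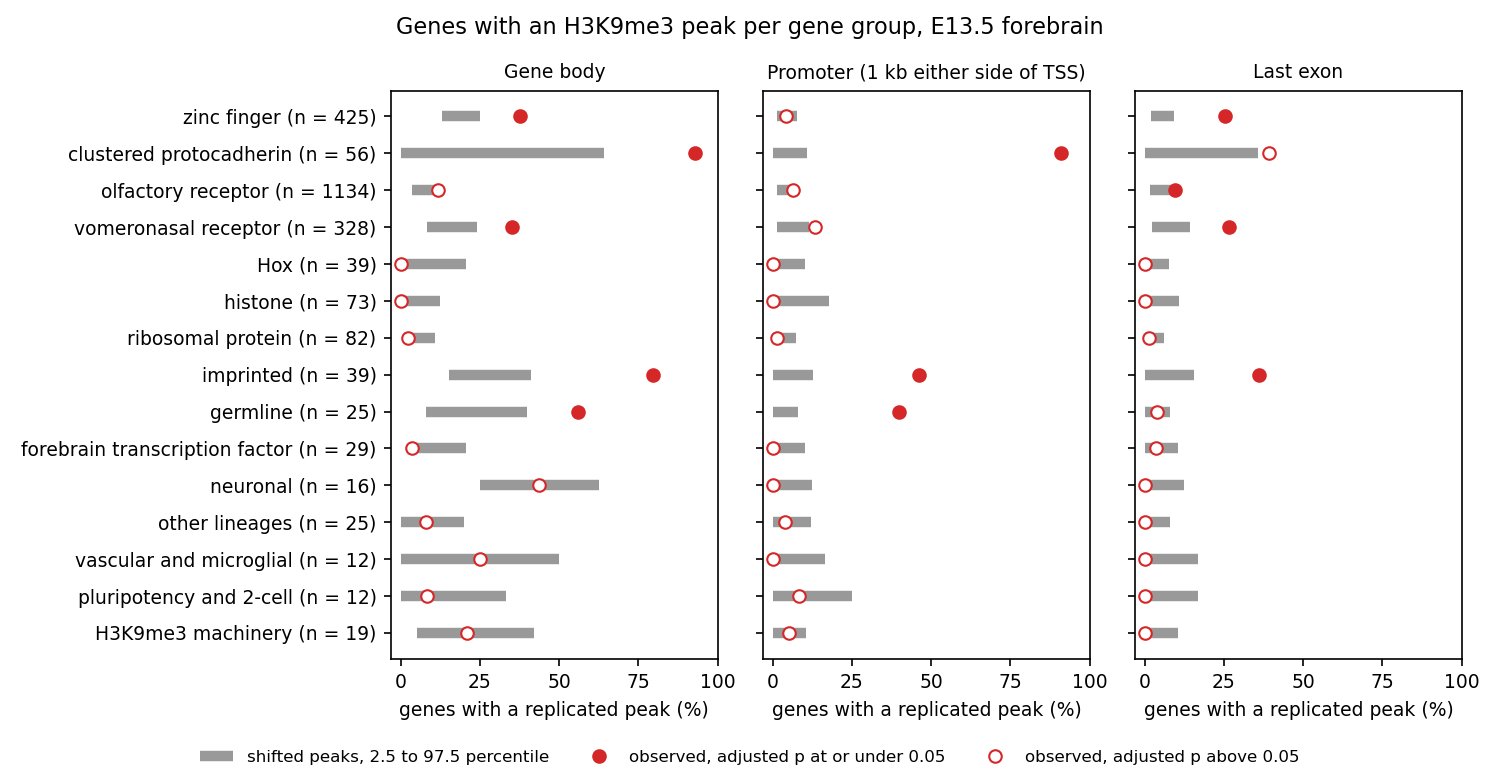
Percentage of genes with a replicated H3K9me3 peak (x axes) in 15 gene groups (rows) at gene bodies, promoters and last exons; grey bars span the central 95% of 10000 circular shifts, and filled circles mark groups with an adjusted p at or under 0.05. Protocadherin promoters reach 91.1% and imprinted promoters 46.2%, while Hox genes stay at 0 in each zone.

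The clustered protocadherins, cell adhesion proteins that give neurons their surface identity and are encoded in the alpha, beta and gamma arrays on chromosome 18, had the most complete coverage of any group. Peaks lay at the promoters of 51 of 56 genes, where shifted peaks gave a mean of 1.401, a ratio of 36.4 (permutation test, two-sided, adjusted p = 1.0e-03). The array from 36930184 to 37841873 on chromosome 18 held 358 replicated peaks covering 284 kb, 31.1% of its length. All 56 genes lie in this stretch, and the shifts move its peaks together, so the promoters are not independent. Peaks also lay away from protocadherin start sites, as between 37565138 and 37645721. Promoters were not compared with the rest of the stretch, so the excess was not shown to be specific to them. Promoter peaks were strongest in the gamma array, with a median fold enrichment of 7.85 over 18 genes, against 4.86 over 11 alpha genes and 4.86 over 22 beta genes. Over last exons 22 genes had a peak, all of them beta genes, a count that did not pass the adjustment (permutation adjusted p = 9.2e-02). The same 22 beta genes all had a promoter peak. How far the 2 zones overlap in these genes was not examined, so a separate signal at their 3′ ends was not shown. Over bodies 52 of 56 genes had a peak against 18.8 shifted (permutation adjusted p = 6.6e-03), but alpha and gamma genes share their 3′ exons and overlap one another, so their bodies are not independent. This ratio of 2.76 fell to 1.73 and 1.78 in the lists of replicates 1 and 2.

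**Figure D3:**
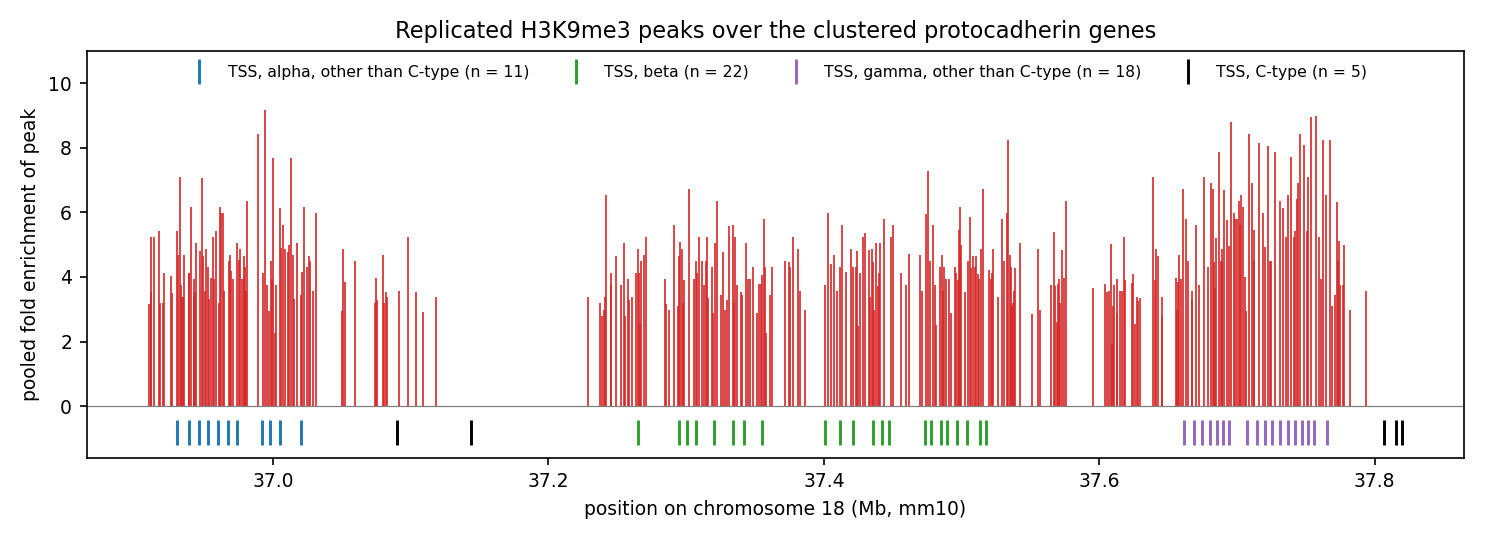
Replicated H3K9me3 peaks along the clustered protocadherin region of chromosome 18 (x axis, Mb, mm10) with the pooled fold enrichment of each peak (y axis, red lines) and the TSS of each gene (ticks below 0, coloured by subcluster). A peak lies within 1 kb of the TSS of each of the 11 alpha, 22 beta and 18 gamma genes outside the C-type, and none lies within 1 kb of the TSS of the 5 C-type genes.

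The 5 promoters with no peak were those of Pcdhac1, Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, the C-type genes that lie at the 3′ ends of the alpha and gamma arrays. This grouping was chosen after the values were seen. The TSSs of Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5 lay in stretches with no replicated peak, from 37118492 to 37228102 and from 37793765 to the end of the gamma array. The split may therefore follow where peaks lie along the region rather than the type of gene, which was not tested. Of the other protocadherin genes, 51 of 51 had a promoter peak in the replicated list. None of the 5 C-type promoters had a peak in the list of either replicate, while Pcdhb9 was the only other gene without one, in replicate 1 alone. The split depends on the window: at 2.5 kb Pcdhac1 also had a peak, from 37091318 to 37092191 with a fold enrichment of 3.55, in the replicated list and in both replicates' lists. The strongest peak of the alpha array, at 36993418 to 36994880 with a pooled fold enrichment of 9.16, lay over a coding exon of Pcdha8 and in introns of Pcdha1 to Pcdha7, and reached 8.05 ± 1.53 in the replicates (mean ± SD, n = 2). In the gamma array a peak at 37755067 to 37759076 reached 8.97 in the pooled list and 8.49 ± 1.27 in the replicates; it spanned the TSS of Pcdhga11 and lay in introns of Pcdhga1 to Pcdhga6, Pcdhgb1 and Pcdhgb2. Because so many gene models overlap these intervals, most of the 25 genes with the highest fold enrichment share these peaks.

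Zinc finger genes, many of which encode DNA-binding repressors, carried the mark at their 3′ ends. A peak lay over the last exon of 108 of 425 genes, against a shifted mean of 21.2, a ratio of 5.11 (permutation test, two-sided, adjusted p = 1.0e-03). At their promoters the difference from the shifts did not pass the test, with 18 genes against 16.8 (permutation adjusted p = 1.0). Of the genes marked over the last exon, 99 had no promoter peak and 9 had both. Along the gene, coverage fell to 0.818% of bases just after the TSS and rose to 6.89% before the gene end. The flanks of these genes were covered as well, with 2.65% at the upstream end of the profile, 4.98% around the gene end and 2.68% at the downstream end, while protein-coding genes in no group stayed between 0.430% and 0.614% throughout. Chromosome 7, which has the most zinc finger genes, had a last-exon peak in 23 of 106 (21.7%), chromosome 13 in 14 of 41 (34.1%), chromosome 17 in 14 of 47 (29.8%) and chromosome 9 in 8 of 20 (40%).

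**Figure D4:**
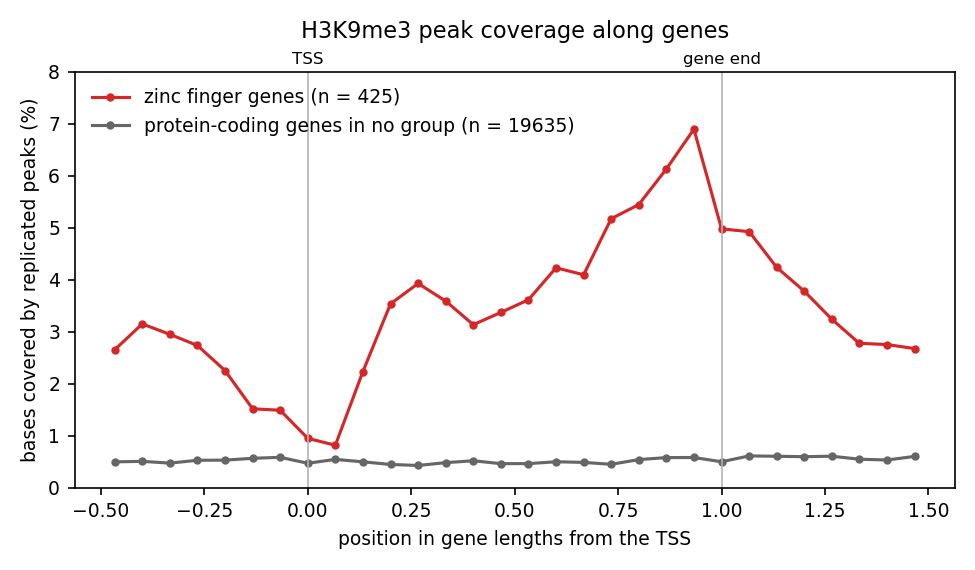
Percentage of bases covered by replicated H3K9me3 peaks (y axis) along genes scaled to the same length (x axis, gene lengths from the TSS), for 425 zinc finger genes (red) and 19635 protein-coding genes in no group (grey). Coverage of zinc finger genes is 0.818% just after the TSS, 6.89% before the gene end and 2.65% and 2.68% at the outer ends of the flanks.

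Over bodies 160 of 425 zinc finger genes had a peak against 78.4 shifted (permutation adjusted p = 1.5e-03). Zfp810 on chromosome 9 had the strongest peak of the group, at 22278094 to 22279350 over coding exon sequence, with a pooled fold enrichment of 9.31 and 8.09 ± 2.43 in the replicates (mean ± SD, n = 2). Zfp354c on chromosome 11 had a peak of 8.94 over coding exon sequence at 50813925 to 50817493, with 8.66 ± 1.496 in the replicates. Zfp146 on chromosome 7 had a peak of 8.97 at 30160676 to 30164343, which spanned the 3′ end of this minus-strand gene (30161269 to 30169750). The summit lay in sequence annotated as 5′ UTR. For this peak the replicates gave 3.81 and 9.79, so its strength rests on replicate 2. Zinc finger genes have many paralogs, and reads shared between copies can add to or remove peaks.

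Imprinted genes, which are expressed from 1 parental allele, carried peaks over 31 of 39 bodies, against 10.8 shifted (adjusted p = 1.5e-03), and at 18 of 39 promoters, against 1.63 shifted, a ratio of 11.1 (adjusted p = 1.0e-03; permutation tests, two-sided). In the list of replicate 1 alone the ratio over bodies fell from 2.865 to 1.777 and still passed (permutation adjusted p = 1.5e-02). The highest promoter peak was at Cdkn1c, an inhibitor of the cell cycle, at 143458866 to 143461173 on chromosome 7, with a pooled fold enrichment of 6.92 and 5.49 ± 0.974 in the replicates (mean ± SD, n = 2). A single peak of 6.14 at 6728079 to 6731286 on chromosome 7 spanned the start sites of the divergent genes Peg3 and Usp29, and reached 5.17 ± 0.436. Sgce and Peg10, another divergent pair, shared a peak of 5.80 at 4746571 to 4747268 on chromosome 6 (4.38 ± 1.65). Gnas had a promoter peak of 5.95 (5.41 ± 1.23), Zrsr1 one of 5.44 (6.37 ± 1.14) and Nnat one of 5.40 (5.998 ± 0.742). Last exons of 14 imprinted genes had a peak against 2.499 shifted (permutation adjusted p = 1.0e-03), and 11 genes had a peak in both zones, among them Cdkn1c, Gnas, Peg10, Usp29, Nnat and Zrsr1. The zones can overlap in short genes: Cdkn1c had 1 peak over its body, which met both zones. The last-exon count is therefore not separate from the promoter count. The paired promoters are counted for both genes, so the 18 promoters hold fewer separate peaks.

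Germline genes, which act in meiosis or germ cell development and are silent in most somatic tissue, had peaks at 10 of 25 promoters, against 0.591 shifted, a ratio of 16.9 (permutation test, two-sided, adjusted p = 1.0e-03). Dazl, an RNA-binding protein of germ cells, had a promoter peak of 5.19 on chromosome 17 at 50293063 to 50294268 (4.58 ± 0.440 in the replicates, mean ± SD, n = 2). Ddx4, a germ cell RNA helicase, had one of 5.03 on chromosome 13 at 112651690 to 112653038 (5.46 ± 0.115). Mael and Sycp1 each had a pooled fold enrichment of 4.67, with 4.34 ± 0.136 and 3.87 ± 0.572 in the replicates. Taf7l on the X chromosome reached 4.11 (4.35 ± 1.23), and Sycp2, Slc25a31 and Rpl10l reached 3.74 each. Over bodies 14 of 25 genes had a peak against 5.70 shifted (permutation adjusted p = 2.2e-03); in the list of replicate 1 alone this excess did not pass the test (ratio 1.35, adjusted p = 0.31). Over last exons 1 gene, Rpl10l, had a peak, the same 1 that met its promoter.

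Vomeronasal receptor genes, which encode pheromone receptors of the vomeronasal organ, had peaks over 115 of 328 bodies, against 48.4 shifted (permutation adjusted p = 2.0e-03). Their last exons were marked in 87 genes against 23.0 shifted, a ratio of 3.78 (adjusted p = 1.0e-03), and their promoters in 44 against 16.4, which did not pass the adjustment (adjusted p = 5.6e-02; permutation tests, two-sided). The 50 kb on either side of these genes were covered about as densely, with 5.67% of bases against 6.80% over last exons and 5.19% over bodies (last exons over flanks 1.2, bootstrap interval 0.895 to 1.58). These flanks include other genes, among them any of the same family, so the comparison cannot tell the genes from the regions that hold them. The excess was not shown to be specific to the genes. The strongest peaks lay in an intron of Vmn2r63 (7.29), in the 3′ UTR of Vmn1r61 (6.73) and in an intron of Vmn2r61 (6.73), all on chromosome 7. Replicates 1 and 2 gave 3.95 and 8.81 for Vmn2r63, 4.52 and 5.55 for Vmn1r61 and 4.43 and 7.502 for Vmn2r61, so the first and last lean on replicate 2. In the replicate 2 list alone the ratio over bodies was 1.52 and did not pass (permutation adjusted p = 5.4e-02); in the replicate 1 list it was 1.56 and passed (2.0e-02), against 2.38 in the replicated list. Promoters passed with the window of 2.5 kb (ratio 2.65, permutation adjusted p = 3.0e-02) and in the replicate 1 list alone (ratio 2.24, adjusted p = 3.7e-02).

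Olfactory receptor genes, the largest group, had peaks over 133 of 1134 bodies against 79.3 shifted (permutation adjusted p = 0.21; 4.2e-02 in the replicate 1 list alone, at a ratio of 1.48) and at 72 promoters against 38.7 (adjusted p = 0.39). Last exons of 110 genes were marked against 46.6 shifted (adjusted p = 4.9e-02; permutation tests, two-sided), the weakest of the calls. It was lost with the stricter q (permutation adjusted p = 0.15), with peaks in both replicates' lists (0.11) and over the last 2 kb of the gene (0.22), where the ratios were 2.27, 2.42 and 2.06 against the 2.36 of the call. It also held in each single-replicate list, with ratios of 2.03 in replicate 1 and 2.09 in replicate 2 (permutation adjusted p = 7.5e-03 in each). Last exons were covered at 2.68% of bases and the 50 kb on either side of the genes at 2.27% (ratio 1.18, bootstrap interval 0.927 to 1.376), so this excess was not shown to be specific to the genes either. These flanks also include other genes, any of the same family among them, so the comparison cannot tell genes from regions. Fisher's exact test, which ignores gene length, put olfactory receptor bodies below other genes, at 0.643 times their share (adjusted p = 2.1e-08). Olfr398 (5.98), Olfr1451 (5.61) and Olfr1490 (5.61) had the highest fold enrichments.

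Hox genes, which pattern the body axis, had a replicated peak in 0 of 39 genes in each zone, and histone genes in 0 of 73. The shifts gave means of 2.19 Hox and 1.77 histone bodies, so an absence of peaks could not be told from chance (permutation adjusted p = 0.65 and 0.87). The single-replicate lists held Hox peaks, above the shifts by ratios of 1.39 in replicate 1 and 2.53 in replicate 2, which did not pass the test. Forebrain transcription factors had a peak in 1 of 29 bodies, that of Bcl11b over its last exon, named after its values were seen, against 3.11 shifted (permutation adjusted p = 0.58), and in 0 of 29 promoters. Ribosomal protein genes had peaks in 2 of 82 bodies, against 4.37 shifted (permutation adjusted p = 0.65): Rpl10l, a testis-expressed copy also counted as germline, at 3.74, and an intron of Rpl3 at 3.18. Fisher's exact test called Hox, histone and ribosomal protein bodies below other genes (adjusted p = 1.8e-03, 2.0e-06 and 6.0e-05); these genes are short.

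Neuronal genes had peaks in 7 of 16 bodies against 7.13 shifted (permutation adjusted p = 1.0) and at 0 of 16 promoters of the gene start. Nrxn1 (5.05, near an internal start site), Rbfox3 (4.47, intron) and Syt1 (4.35, intron) had the highest. Fisher's exact test put neuronal bodies above other genes at 2.45 times their share (adjusted p = 2.2e-02); these genes are long. Genes of other lineages had peaks in 2 of 25 bodies, Serpina1a (3.93) and Tal1 (3.74), vascular and microglial genes in 3 of 12, Pdgfrb (5.58), Cx3cr1 (2.75) and Pecam1 (2.62), and pluripotency and 2-cell genes in 1 of 12, Esrrb (4.30, seen in replicate 1 only). Of the H3K9me3 machinery 4 of 19 genes had a peak over the body, Setdb1, Kdm4c, Atf7ip and Fam208a, and Fam208a, part of the HUSH silencing complex, had one at its promoter (4.11; 4.75 in replicate 1 and 2.30 in replicate 2). Dppa3, a pluripotency gene, and Serpina1a had the only promoter peaks of their groups; Dppa3, Setdb1, Kdm4c and Atf7ip were named after their values were seen. None of these groups passed the test in any zone (adjusted p = 1.0 in each; permutation tests, two-sided).

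The strongest peaks over protein-coding genes lay at single genes as well as in clusters. Klf14, an intronless transcription factor gene on chromosome 6, had the highest pooled fold enrichment, 11.2, in a peak at 30956271 to 30959211 that spanned its promoter and body, with 10.6 ± 0.224 in the replicates (mean ± SD, n = 2). Tcfl5, a transcription factor gene on chromosome 2, followed with a promoter peak of 11.03 at 180642650 to 180644819 (9.81 ± 0.0293). Ccdc177 on chromosome 12 had a peak of 10.8 over coding exon sequence at 80755472 to 80759432 (9.48 ± 0.427). Gm21887, near the end of chromosome X, had a promoter peak of 10.3 at 170008970 to 170010048, for which the replicates gave 9.69 and 5.02. Its −log10 q was 143.2, against 40.69 for Klf14, and regions of unusually high signal were not filtered out. By group, the peaks of protocadherin genes had a median fold enrichment of 4.67 and those of zinc finger genes 4.10, both above nearly all random sets of genes with a peak (percentile 100), against a median of 3.59 over all replicated peaks. The random sets drew genes independently over the genome. Protocadherin genes lie in a single stretch and share peaks, so the random sets may vary too little for groups whose genes lie close together. Imprinted, germline and vomeronasal genes each had a median of 3.74, at percentiles 70.5, 71.1 and 69.7, and olfactory receptor genes 3.55, at percentile 12.6. Ranked by −log10 q, vomeronasal genes stood at percentile 39.0 and olfactory receptor genes at 38.5, and olfactory receptor genes stood at 44.6 and 67.7 in the lists of replicates 1 and 2. Germline genes stood at 90.1 in the list of replicate 1 and 44.4 in that of replicate 2, and vomeronasal genes at 97.8 and 96.4.

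Merging replicated peaks at gaps of up to 10 kb gave 14958 domains, of which 73.1% held a single peak and 91 were at least 100 kb long. The longest spanned 330 kb of chromosome 13, from 61405557 to 61735119, with 153 peaks over the placental cathepsin genes Ctsm and Cts3. On chromosome 7, 317 kb from 17884631 to 18201898 covered Ceacam11, Ceacam12 and Ceacam13, 248 kb from 17595219 to 17843681 covered Ceacam5 and Ceacam14, and 279 kb from 33776538 to 34055343 covered the secretoglobin genes Scgb2b26, Scgb2b27 and Scgb1b27. Further secretoglobin genes lay in 245 kb from 31284493 to 31529605, and Vmn1r66 and Vmn1r67 in 246 kb from 10233135 to 10479185, both also on chromosome 7. On chromosome 4, 247 kb from 144346335 to 144593258 held the Pramef12 and Pramef20 genes, and 261 kb from 121475273 to 121736596 held Gm12887. The other domains of this size were 263 kb on chromosome 9 from 36290152 to 36552821, with 3 predicted genes, and 239 kb on chromosome 12 from 114245697 to 114484874, with 0 protein-coding genes. Only genes annotated as protein-coding were counted, so genes of other annotated types may lie in these domains. Lengths depended on the gap: at 5 kb only 6 domains reached 100 kb and the longest was 166 kb, and at 20 kb 128 did and the longest was 1025 kb. The single-replicate lists gave 34034 and 33288 domains, with longest domains of 511 and 473 kb in replicates 1 and 2.

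The densest 1 Mb window was the protocadherin window of chromosome 18 from 37000001 to 38000000, with 254 kb of replicated peaks and 215 ± 9.40 kb in the replicates (mean ± SD, n = 2). Windows over the Pramel and Oog genes of chromosome 4 from 144000001 (214 kb; 174 ± 11.01), a window of chromosome 12 from 114000001 with 0 protein-coding genes (209 kb; 178 ± 17.3) and the Scgb genes of chromosome 7 from 33000001 (209 kb; 167 ± 10.7) came next. They were followed by the cathepsin window of chromosome 13 from 61000001 (196 kb), the Psg and Ceacam windows of chromosome 7 from 17000001 (182 kb) and 18000001 (153 kb), chromosome 4 from 121000001 (163 kb), the Vmn2r genes of chromosome 17 from 19000001 (154 kb) and the Cyp3a genes of chromosome 5 from 145000001 (150 kb). Genes of types other than protein-coding were not listed for these windows, so the chromosome 12 window is not shown to be free of genes. Of 2737 windows, 109, or 3.98%, held 50% of all covered bases, against 296 and 259 in the lists of replicates 1 and 2. Of the 10 densest windows, 7 were also among the first 10 in the replicate 1 list and 9 in the replicate 2 list.

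Replicated peaks were richer in G and C than the shifted intervals, with 46.1% against 42.1 ± 0.330%, and had fewer CpG dinucleotides than their base content gives, with an observed over expected ratio of 0.174 against 0.193 ± 0.00328 (mean ± SD of 100 shifts; permutation test, two-sided, p = 2.0e-02 for both, the smallest that 100 shifts give). The soft-masked share, bases marked as repeats in the reference, was 32.8% against 33.9 ± 0.751%, a difference that did not pass the test (permutation p = 0.14). In the lists of replicates 1 and 2 this share was 32.1% and 32.7%, below all of their shifts (permutation p = 2.0e-02 in each). Repeats in which reads cannot be placed are not represented in a peak list, so this share says nothing of the mark over such repeats.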

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

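The comparison of peak numbers on X with those on autosomes and the comparison of last exons with the flanks of the same genes were tests chosen only after the result was seen. The test of −log10 p on X was added once the first tests on X had been seen.

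Replicated peaks also lay outside the assembled chromosomes, in sequence that no comparison used: 290 of them, on 25 unplaced or unlocalized sequences. They are listed because the count is above the limit of 3 that a count of 0 allows, a low bar and no test, since the lists of replicates 1 and 2 also held 380 and 411 peaks there. Their median fold enrichment was 4.11 and the highest 9.75. A single unplaced contig held 69 of them, with a −log10 p of up to 194.9, the highest in the pooled list.

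Replicate 2 held 1203 more peaks on chromosome X than replicate 1. A higher overall yield is argued against, since the ratio of peak numbers on X was 1.675 and the autosomes lay between 0.963 and 1.05, and so are a few regions of X, since the 5 windows with the largest excess held 17.4% of it and 132 of 172 windows had more peaks in replicate 2. A different share of X-bearing DNA relative to the control stays open: the median log2 ratio of fold enrichment (replicate 2 over 1) of 439 X peaks was 0.04, within the autosome medians of 0.04 to 0.12, which was first read as excluding it, but its bootstrap interval of 0.04 to 0.14 reaches past them, so that reading was withdrawn after the value was seen. More X-derived reads in both the immunoprecipitate and the control of replicate 2 stay open as well, with a median log2 ratio of −log10 p of 0.06 (0.05 to 0.15) against 0.05 to 0.14 on autosomes. The −log10 p of a peak also depends on sequencing depth, which is unknown for both replicates. The labels give no proportion of the sexes in either pool, and no biological explanation was tested.

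Zinc finger genes carried peaks over the last exon. Reads shared between paralogs are argued against as the whole cause: among 245 genes whose last exon consists of at least 95% unique 32-mers, 57 had a peak, against a shifted mean of 12.2 and an upper limit of 24 for the central 95% of shifts. Peak-rich surroundings are argued against as the whole cause too, since last exons were covered 3.51 times as densely as the 50 kb on either side of the same genes (11.9% against 3.40% of bases; bootstrap interval over 1 Mb blocks 2.77 to 4.495, above the bound of 1.5). The flanks were themselves covered more than those of other protein-coding genes (0.696%), so surroundings stay open as part of the excess. Similarity between zinc finger exons short of identical 32-mers was not examined, and no biological explanation was tested because the design has a single group.

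Few peaks were shared between replicates although 1 Mb windows were closely related. Weak peaks near the calling threshold are a candidate explanation: 95.3% of the 1000 replicate 1 peaks with the smallest p overlapped a replicate 2 peak, and the share fell to 73.7%, 48.7% and 22.8% in successive classes of larger p. Shifts gave at most 11.5% for these 1000 at an overlap of 1 bp, but limiting both lists, which also sets a new threshold, raised the shares little: to 36.8% and 31.69% at a −log10 q of at least 2 and to 33.3% and 32.7% for the 20000 peaks with the smallest p. Broad regions broken into peaks at different places may add to it: 51.4% of the 49108 unshared replicate 1 peaks had a replicate 2 peak within 5 kb, against at most 21.8% in 1000 shifts. The shifts also move peaks out of the dense windows that the replicates share, so this excess cannot tell broken regions from shared windows. Both explanations can hold at once, and no biological one was tested.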

How the results depend on the processing

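The alternatives for promoters and last exons other than the 2.5 kb window and the last 2 kb of the gene were tests chosen only after the result was seen. Of 321 alternative values, 247 stayed the same, 5 lost the call, 8 gained one, 29 moved and 32 changed direction. Those that changed direction were in groups that did not pass the main test in that zone. Some had main ratios near 1 and others far from it, such as Hox genes at 0. The same means the same direction and side of the threshold for a test, within 1.5 times for the number of domains, and within 1 SD of the replicates or a binomial interval for other values. All 8 values of the overlap between replicates and all 12 feature shares kept theirs. The cause was not tested unless stated.

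Of replicated peaks, 84.69% lay in replicate 1, 87.73% in replicate 2 and 73.38% in both at 1 bp, and 62.47%, 67.89% and 40.81% when 50% of both intervals had to overlap. At a −log10 q of at least 2, chromosome 15 had 2.914 kb per Mb. The longest domain was 165.9 kb at a gap of 5 kb and 1025.3 kb at 20 kb, by construction. Ranked by −log10 q, strength percentiles were 38.52 for olfactory, 38.97 for vomeronasal and 49.29 for imprinted genes.

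Fisher's exact test ignores gene length and gave ratios over bodies of 0.6431 for olfactory receptors and 0.1358 for ribosomal proteins, 0 for Hox and 0 for histone genes, 2.447 for neuronal genes and 1.176 for the H3K9me3 machinery. At the stricter q, body ratios were 1.024 for neuronal, 1.037 for other-lineage and 0.3812 for vascular and microglial genes, and the last-exon ratio of olfactory receptors was 2.267. With peaks in both replicates' lists, body ratios were 1.26 for other lineages and 1.135 for the machinery, the promoter ratio of other lineages was 0 and the last-exon ratio of olfactory receptors 2.423. With 50% of the peak within the gene, other lineages had 1.067. The 2.5 kb window gave promoter ratios of 2.651 for vomeronasal receptors and 0.6993 for other lineages, and the last 2 kb gave 2.059 for olfactory receptors and 0 for forebrain transcription factors.

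Leaving out each replicate leaves the longer list of the other. Body ratios ranged from 0.6837 to 1.011 for the machinery, 1.386 to 2.534 for Hox, 1.347 to 1.72 for germline (call lost without replicate 2), 0.9348 to 1.042 for neuronal, 1.481 to 1.489 for olfactory, 1.777 to 2.005 for imprinted (calls kept), 0.4818 to 1.431 for other-lineage, 1.157 to 1.197 for pluripotency and 1.518 to 1.559 for vomeronasal genes (call lost without replicate 1). Promoter ratios ranged from 0.9823 to 2.904 for the machinery, 1.183 to 1.814 for Hox, 0 to 0.7262 for other-lineage, 2.147 to 2.242 for vomeronasal and 0.8222 to 0.9107 for zinc finger genes. Last-exon ratios ranged from 1.091 to 1.139 for the machinery, 0.8065 to 1.463 for Hox, 0.6892 to 0.7194 for forebrain transcription factors and 0 to 1.795 for other lineages. Coverage in kb per Mb ranged from 4.708 to 4.778 on chromosome 15, 12.84 to 14.1 on 17, 10.32 to 11.11 on 4, 19.41 to 21 on 7, 2.548 to 4.286 on X and 0.1142 to 0.1402 on Y. Strength percentiles ranged from 51.32 to 78.21 for imprinted, 44.55 to 67.71 for olfactory, 96.38 to 97.76 for vomeronasal and 100 to 100 for zinc finger genes. Soft-masked shares were 32.11 to 32.65%, domains numbered 33288 to 34034 and the longest measured 472.7 to 511.2 kb. Depth is unknown, so it cannot be said how many weak peaks either replicate missed.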

Other observations

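The description of the strongest peaks and the test of gene families were chosen only after the data were seen.

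The strongest pooled peaks by p lay at sites other than the gene groups. Of the 10 with the smallest p, 3 lay on chromosome 11 from 3184201 to 3200102 over Sfi1 and Drg1, with fold enrichments of 4.10, 4.08 and 3.97, and 2 lay on chromosome 17 from 39842961 to 39848902 over an annotated ribosomal RNA gene, with 3.35 and 3.20. A peak on chromosome 13 from 119597589 to 119598361 met Tmem267 (fold enrichment 7.83), the Gm21887 promoter peak on X had 10.3, and 3 lay on unplaced contigs. The fold enrichments on chromosomes 11 and 17 were near the median of 3.59 over all replicated peaks, yet their −log10 p lay between 138.6 and 184.2. Regions of unusually high signal were not filtered out here. Whether these peaks reflect H3K9me3 or high signal in such regions was not tested. The 100 replicated peaks with the smallest p had 30.1% of their bases soft-masked, against 32.8% over all replicated peaks, and all 100 had a peak in both replicates.

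Gene families outside the fixed groups were tested, grouped by the letters that open their symbols. Of 253 families with at least 10 members, 0 passed an adjusted p of 0.05 at gene bodies in the circular shift test. An unadjusted p under 0.05 was found in 14. By chance this threshold would pass a mean of 12.65 if the test were calibrated. In the simulations 2.93% of the group tests at gene bodies passed it, so the number by chance may be lower. Whether 14 exceeds chance was not tested. Among the 14, Nlrp genes, which encode inflammasome and oocyte proteins, had a peak in 12 of 17 bodies against 5.40 shifted (permutation adjusted p = 0.63). Klra genes, natural killer cell receptors, had peaks in 8 of 11 against 1.51, Scgb genes in 11 of 34 against 2.27 and Skint genes in 10 of 11 against 4.26 (permutation adjusted p = 0.77 in each). At the other end, Nup genes of the nuclear pore had peaks in 0 of 21 bodies against 5.43 shifted (permutation adjusted p = 0.63) and Mrpl genes of the mitochondrial ribosome in 0 of 49 against 4.33 (adjusted p = 0.77). With 10000 shifts a single family could reach an adjusted p of 0.0506 at best, so none could pass alone; the lowest unadjusted permutation p found was 3.0e-03.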
